A study of Oryza sativa with 6 samples.

How the data were processed

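RNA from flowers was measured on 6 arrays, 3 of the osmads6-1 mutant and 3 of wild type, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made with the Affymetrix 3 prime IVT express kit. The deposited values are on a log2 scale; per the submitters' processing notes the tools were Partek and RMA, with no versions, roles or order. RMA subtracts background, makes the distributions of the arrays alike and summarises probes per probe set, so a change shared by most transcripts is removed, and changes of dim probe sets are compressed. The log2 scale was read from the values, which share like quantiles across samples. Scanner files were not used here, and no detection calls were used, so dim values carry no background bound. The genome build is not given in the sources used here, and no coordinates are printed.

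Probe sets were named through the platform annotation, with symbols and synonyms updated by gene ID through the RefSeq gene table of assembly ASM3414082v1. Of 57258 tested probe sets, 22436 had 1 gene symbol, 95 had several and 34727 had none in that table and are unnamed here. All 22436 gene IDs matched, giving 17905 genes, of which 2458 had a name beyond an identifier. A named gene with a group mean under the median of every array is called dim, a bound chosen after values were seen, and no fold is given for it. A gene was represented by its single-gene probe set with the highest mean over the 6 samples.

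Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the single factor, two-sided, all probe sets other than the 123 controls), with Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 18 lists, and again with a correlation estimated per list. Tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the departures given here. The rule named OsMADS6, any floral homeotic MADS gene, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with groups that do not overlap and a named product, and in every other list up to 4 members with the smallest p. Since the tables hold no product descriptions, a named product was read as a gene name beyond an identifier. For the same reason list members were matched by symbol or synonym and chromosome, and description patterns were rewritten as name patterns after the annotation was seen and before any test result; of 151 hand-listed members, 89 were measured, 52 were not matched by name and 10 had no single-gene probe set. Of the list members measured, 11 stand in 2 lists, SPL14 and YAB1 among them, so those lists are not independent of each other.

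The functions were tested on simulated data for this comparison, a test made only after they had first been run on the real values. It covered 57258 probe sets, 200 of them changed, with the real means and the spread of each probe set as moderated by eBayes. At a true log2 change of 0.5, 47.8% of the changed probe sets were recovered, at 1 98.5% and at 2 100%, none with the wrong sign; 12 unchanged probe sets were called, and 0 were called when none was changed. A list shifted by 0.25 was called higher, and no other list was. The simulation draws genes independently, unlike real genes of a list. Moderated spreads are more even across probe sets than the residual ones, so the shares recovered may be too high.

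The alternatives chosen in advance were quantile normalization of the table again, centring each sample on its median, a filter at a mean log2 signal of 6 in either group, an intensity trend with robust estimation, array weights, the replicate number as a block, leaving out each sample in turn, an adjusted p of 0.01, a test against a 1.5-fold change, an estimated correlation in camera, and the mean of a gene's probe sets. Control probe values were compared by exact permutation. Lists of ABA and dehydration genes and of replication genes were added after the values were seen and stand only in the closing section, where OsPP2C30, OsPP2C08, OsPP2C09, Osem, OsABF2, OsABA8ox1, OsMCM2, OsMCM3, OsMCM4, OsMCM5, OsMCM7 and OspolD1 lie outside the rule for named genes and were chosen after their values were seen. Which of the genes the rule allows are named was also chosen with their values in view. The adjusted p was taken as the value followed for each list across alternatives, in place of the list median, after first results were seen. All tests of explanations there were also written after their results were seen.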

Results

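Gene expression was measured on the Affymetrix rice genome array in flowers of the rice mutant osmads6-1 and of wild type, with 3 samples of each. The samples were taken at spikelet stage Sp6, the stage of the standard spikelet series at which stamen primordia form. OsMADS6 is a MADS-box transcription factor gene of the AGL6-like class. The 123 array control probe sets were left out, and 57258 probe sets were tested. Values were RMA signals on the log2 scale, and the median signal per sample lay between 5.51 and 5.58. Pearson's r between samples, taken across probe sets, which are not independent replicates, was 0.997 between osmads6-1 replicates 1 and 3 and 0.990 between osmads6-1 replicate 2 and wild type replicate 1. Within-group and between-group values overlapped. Osmads6-1 replicate 1 and wild type replicate 2 gave 0.9960. Lower values came from osmads6-1 replicates 1 and 2 (0.9957), osmads6-1 replicates 2 and 3 (0.9956) and wild type replicates 1 and 3 (0.9954). No pair of samples held the same values throughout. The labels name 3 replicates per group but do not say whether they came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

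The comparison asks which transcripts differ between osmads6-1 and wild-type flowers of the same stage. The transcript of the mutated gene itself was not lower in the mutant. The OsMADS6 probe set gave 12.07 ± 0.18 (SD, n = 3) in osmads6-1 (12.12, 12.22 and 11.87 in replicates 1, 2 and 3) and 11.91 ± 0.10 (SD, n = 3) in wild type (11.87, 11.84 and 12.03). The difference of 0.16 on the log2 scale did not pass the test (limma, adjusted p = 0.616). The nature of the lesion is not given in the labels, and a lesion that leaves the messenger RNA in place, or that lies away from the probe set, would not show here. This probe set therefore checks nothing about the sample labels.

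Among named genes that passed the test, the largest measured falls in osmads6-1 were those of floral homeotic MADS-box genes. Among 22 measured members of the floral homeotic MADS list, 8 fell, 1 rose and 13 did not pass the test; adjusted over the list alone, 9 fell and 4 rose. Both measured AGAMOUS-like genes of the C class fell: OsMADS58 (LOC4338067) from 9.25 ± 0.32 to 4.76 ± 0.62 (SD, n = 3 per group) and OsMADS3 (LOC9271572) from 7.30 ± 0.26 to 4.35 ± 0.30. The B-class genes also fell. OsMADS16, the APETALA3-like gene, was 8.41-fold lower, at 7.93 ± 0.55 in osmads6-1, and of the PISTILLATA-like pair OsMADS4 was 3.68-fold lower (9.83 ± 0.12 to 7.96 ± 0.21) and OsMADS2 1.44-fold lower (11.88 ± 0.07 to 11.35 ± 0.14). The SEPALLATA-like genes OsMADS7 and OsMADS8 were 11.6-fold and 6.28-fold lower, from 11.54 ± 0.12 to 8.01 ± 0.70 and from 11.22 ± 0.14 to 8.57 ± 0.58. OsMADS13, a D-class gene of the ovule, fell from 4.73 ± 0.21 to 3.62 ± 0.21. The osmads6-1 values of OsMADS58 and OsMADS3, and both group values of OsMADS13, were dim, here meaning under the median signal of every array. No background level was known, so the size of their falls is left open and no fold is given. The limma adjusted p was 0.000289 for OsMADS3, 0.00045 for OsMADS58 and OsMADS4, 0.00132 for OsMADS16, 0.00193 for OsMADS7, 0.00341 for OsMADS8, 0.0121 for OsMADS13 and 0.0425 for OsMADS2.

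The member that rose was OsMADS17, the other AGL6-like gene and closest relative of OsMADS6, from 10.25 ± 0.09 to 11.09 ± 0.24 (SD, n = 3), 1.78-fold higher (limma, adjusted p = 0.0237). Other members of the same family did not pass the test. The SEPALLATA-like genes OsMADS1 and OsMADS34 differed by 0.35 each on the log2 scale (adjusted p = 0.158 and 0.102), and the APETALA1-like genes OsMADS14, OsMADS15 and OsMADS18 by 0.26, 0.04 and 0.34 (adjusted p = 0.423, 0.909 and 0.229). OsMADS1 and OsMADS34 passed with an intensity trend and robust estimation (0.0392 and 0.027), and OsMADS34 also with dim probe sets left out (0.0498). The difference of OsMADS15 turned to -0.0071 without wild type replicate 1. Camera called the list lower (adjusted p = 0.0379), a call lost with an estimated correlation (adjusted p = 0.595). The mean difference was -0.84 but the median only -0.06. Some members fell strongly while 13 did not pass, and differences were positive in 10 members and negative in 12. The median lay between -0.03 without wild type replicate 1 and -0.16 without wild type replicate 3. The call was also lost with quantile normalization, the dim filter, array weights and the mean of probe sets (adjusted p 0.0526 to 0.09), and without osmads6-1 replicate 3 (adjusted p = 0.0725) and without wild type replicate 3 (adjusted p = 0.0606). OsMADS58, OsMADS3, OsMADS16, OsMADS4, OsMADS7 and OsMADS8 passed the test with any single sample left out. OsMADS13 did not without wild type replicate 2 (adjusted p = 0.0553), OsMADS17 passed only without osmads6-1 replicate 1 or replicate 3 (0.0387 and 0.017) and reached 0.116 without wild type replicate 2, and OsMADS2 passed only without osmads6-1 replicate 1 (0.0317) and reached 0.157 without osmads6-1 replicate 3.

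**Figure D1:**
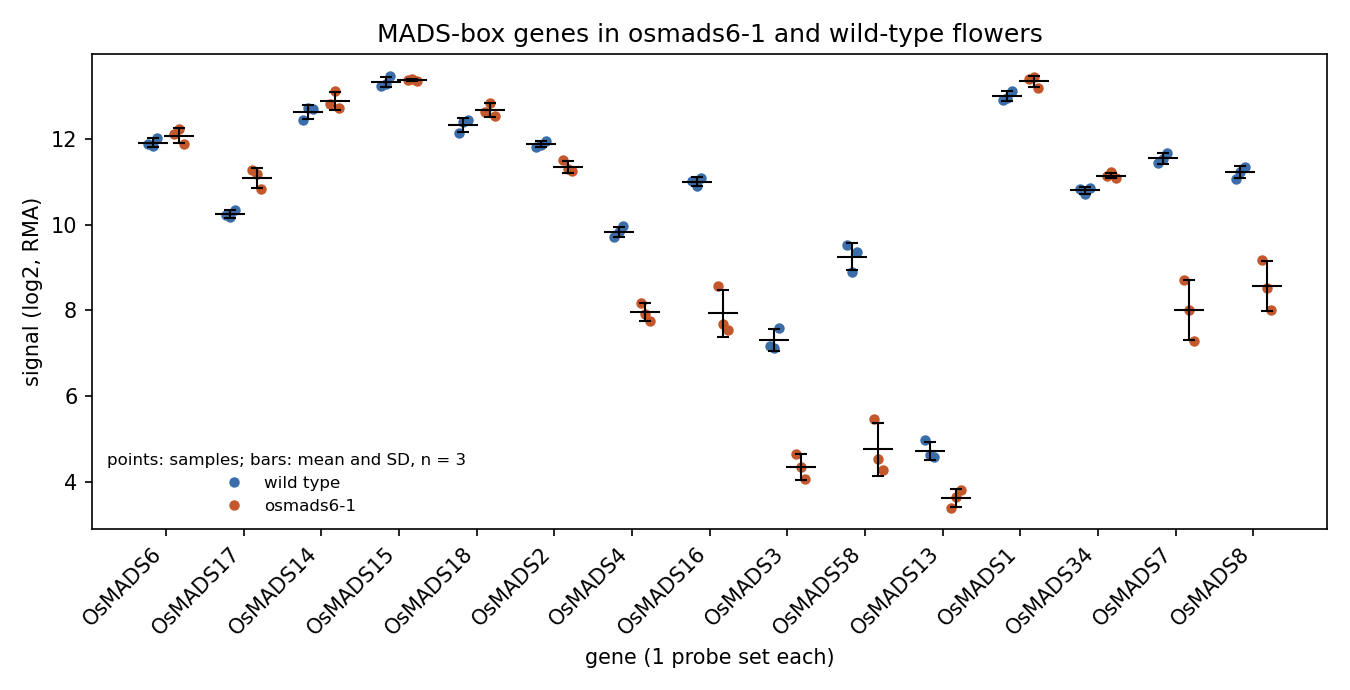
Signal of 15 MADS-box genes in each sample (vertical axis, log2 RMA signal, 1 probe set per gene), with wild type in blue and osmads6-1 in orange; points are samples and bars the mean and SD of 3 samples. OsMADS58 lay at 9.25 in wild type and 4.76 in osmads6-1, while OsMADS6 lay at 11.91 and 12.07.

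Over the whole array, 668 probe sets differed (limma, Benjamini-Hochberg adjusted p under 0.05), 443 higher and 225 lower in osmads6-1, of which 116 and 53 changed at least 2-fold. The groups did not overlap in 19.8% of all tested probe sets, against 10% expected by chance. Named genes were ranked only if they passed the test with groups that did not overlap. The 8 named genes with the largest measured rises were OsTPP1, a trehalose-6-phosphate phosphatase (8.38-fold, to 8.87 ± 1.14 in osmads6-1, SD, n = 3), PP2C68, a protein phosphatase 2C (5.17 ± 0.14 to 8.12 ± 0.57), JAZ13, a jasmonate ZIM-domain repressor (5.02 ± 0.06 to 7.97 ± 1.02), the dehydrins RAB21 and RAB16B (5.31-fold and 4.30-fold), OsHsf-05, a heat stress transcription factor (4.91-fold), CML16, a calmodulin-like protein (4.76-fold), and OsSWEET15, a sugar transporter (4.24-fold). Their adjusted p ranged from 0.00193 for PP2C68 to 0.0396 for RAB16B. A second RAB21 probe set rose by 2.30 on the log2 scale (adjusted p = 0.0394). The wild-type values of PP2C68 and JAZ13 were dim, so the size of their rises, and with it their rank, is left open. OsTPP1 and RAB16B were not dim by group mean, but each had a wild-type replicate under the median of every array. In wild type replicates 1, 2 and 3, OsTPP1 gave 6.14, 5.40 and 5.87, and RAB16B gave 6.33, 6.80 and 5.08. With no background level known, their folds are uncertain as well. The 8 largest measured falls among named genes that passed the test were 7 of the MADS-box genes above and OsORC3. OsORC3 is a subunit of the origin recognition complex that marks sites of DNA replication. It fell by 1.25 on the log2 scale, from 8.68 ± 0.05 to 7.43 ± 0.34 (limma adjusted p = 0.0118). Probe sets without a gene name were looked at after their values were seen. The 5 with the largest measured falls had osmads6-1 means of 3.46 to 4.77, all dim, so their sizes were not ranked against those of named genes. The 5 with the largest measured rises had wild-type means of 4.47 to 6.76. A probe set without a gene symbol (6.76 to 9.76) and LOC4325688 (5.66 to 8.48) were not dim in wild type. They rose by 3.00 and 2.83 on the log2 scale, between OsTPP1 (3.07) and RAB21 (2.41). The others were dim and were not ranked.

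The count of 668 depended on the samples: it was 734 without osmads6-1 replicate 1, 277 without osmads6-1 replicate 2, 140 without osmads6-1 replicate 3, 191 without wild type replicate 1, 101 without wild type replicate 2 and 133 without wild type replicate 3, and the share of calls that were higher moved from 66.3% to between 50.5% and 70.8%. Of the 8 rises, PP2C68 and CML16 passed in all 6 of these fits. OsTPP1 passed only without osmads6-1 replicate 1 (adjusted p = 0.000447), where its difference was 3.72 on the log2 scale, against 3.07 with all samples. The lowest OsTPP1 difference with a sample left out was 2.64. RAB16B passed only without wild type replicate 3 (0.0243), and RAB21 only without osmads6-1 replicate 1 or 2 (0.0246 and 0.0388). JAZ13 did not pass without wild type replicate 1, 2 or 3 (0.0632, 0.1 and 0.0785), OsHsf-05 without osmads6-1 replicate 3 (0.0657), and OsSWEET15 without wild type replicate 2 (0.0515). OsORC3 did not pass without wild type replicate 2 (0.071) or replicate 3 (0.0536).

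**Figure D2:**
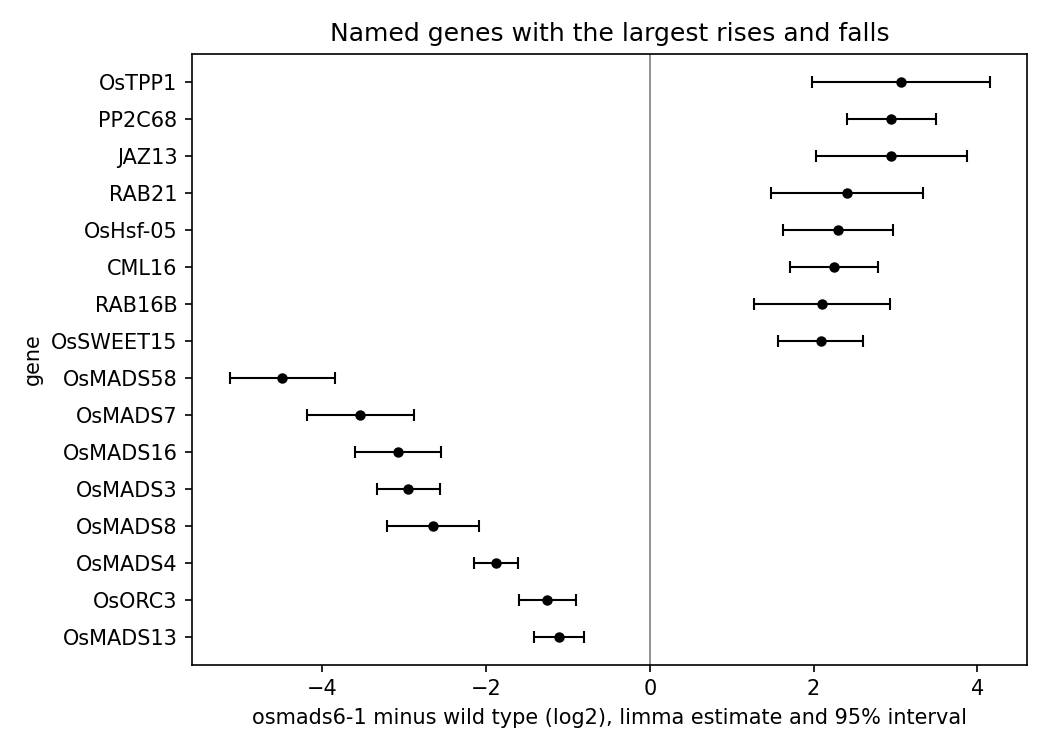
Difference between osmads6-1 and wild type (horizontal axis, log2) for the 8 largest rises and 8 largest falls among named genes that passed the test. Points are limma estimates from 3 samples per group and bars their 95% intervals. Among genes not dim in either group, the estimates run from 3.07 for OsTPP1 to -3.54 for OsMADS7. Those of PP2C68, JAZ13, OsMADS58, OsMADS3 and OsMADS13 rest on a dim group mean, which leaves their size open. OsTPP1 and RAB16B each had a wild-type replicate under the median of every array, so their size is uncertain too.

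A few jasmonate and expansin genes rose. Camera called each list higher (adjusted p = 0.0379 each, medians 0.04 and 0.10), a call lost at adjusted p = 0.595 for each with an estimated correlation. Of 32 measured jasmonate genes, 3 rose and none fell; adjusted over the list alone, 6 rose. The 3 were repressors of the JAZ family: JAZ13, JAZ10 (8.22 ± 0.27 to 9.64 ± 0.61, SD, n = 3, 2.68-fold) and JAZ4 (1.44-fold, adjusted p = 0.0294). A second probe set of JAZ10 and of JAZ4 did not pass (adjusted p = 0.103 and 0.109), though both lay higher in the mutant. JAZ4 passed in none of the fits with a sample left out (highest adjusted p 0.132, without wild type replicate 2), and JAZ10 only without osmads6-1 replicate 1 (0.00556), nor did it pass with array weights (0.0603). Of 29 expansins, which loosen cell walls, 4 rose and none fell; adjusted over the list alone, 6 rose and 2 fell. EXPB11 was 2.45-fold higher (8.47 ± 0.07 to 9.76 ± 0.17, adjusted p = 0.00193) and EXPB6 1.68-fold higher (adjusted p = 0.0161). EXPA5 and EXPA7 were 1.62-fold and 1.36-fold higher (adjusted p = 0.0403 and 0.049), and both lost the call when each sample was centred on its median (0.0504 and 0.0603). EXPB11 passed with any sample left out, EXPA5 only without osmads6-1 replicate 2 (0.0258), EXPA7 in none of these fits (0.0717 to 0.171), and EXPB6 not without osmads6-1 replicate 3 (0.0627), wild type replicate 2 (0.0918) or wild type replicate 3 (0.0685). Of 2 dimmer EXPA7 probe sets neither passed (adjusted p = 0.928 and 0.274), the former with a difference of -0.04. Both list calls were also lost with quantile normalization (0.0614 and 0.0735) and with array weights (0.116 each), and the expansin call with the mean of probe sets (0.0526). The jasmonate median lay between 0.05 without wild type replicate 1 and 0.11 without wild type replicate 2. The jasmonate call was lost without osmads6-1 replicate 2 (adjusted p = 0.0654) and without wild type replicate 1 (0.227), and the expansin call without osmads6-1 replicate 3 (0.085), wild type replicate 1 (0.224) or wild type replicate 3 (0.0606).

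Among 16 floral and meristem regulators, 2 rose, none fell and 14 did not pass; adjusted over the list alone, 2 rose and 2 fell. RFL, the rice LEAFY homologue, was 1.39-fold higher (12.10 ± 0.07 to 12.58 ± 0.04, SD, n = 3, limma adjusted p = 0.0356) and SPL14, an SBP-box factor of panicle branching, 1.52-fold higher (adjusted p = 0.0473). YAB1, a YABBY gene, differed by -0.84 on the log2 scale and did not pass (limma adjusted p = 0.0624), though it did without osmads6-1 replicate 1 (0.00439). It also passed in 2 of 6 settings that kept all samples (lowest limma adjusted p 0.0428). Of 28 SBP, TCP and GRF factors, SPL14 and GRF4 (1.34-fold, adjusted p = 0.0462) rose; adjusted over the list alone, 3 rose and 3 fell. Single members rose in 4 further lists: TDL1A, an anther cell-fate ligand, among 8 early anther and meiosis genes (1.49-fold, adjusted p = 0.0331), SLRL1, a DELLA-like protein, among 9 gibberellin genes (1.49-fold, 0.0475), GH3.1, an auxin-conjugating enzyme, among 59 auxin genes (1.49-fold, 0.021), and WRKY71 among 19 WRKY and pathogenesis-related genes (4.86 ± 0.19 to 6.79 ± 0.81, adjusted p = 0.0381). Wild-type WRKY71 was dim, which leaves the size of its rise open, and a second probe set of it did not pass (adjusted p = 0.312). RFL, SPL14, GRF4 and SLRL1 passed in none of the 6 fits with a sample left out, where the lowest adjusted p was 0.0744, 0.0545, 0.0702 and 0.0917. TDL1A, GH3.1 and WRKY71 passed only without osmads6-1 replicate 1 (0.0336, 0.0299 and 0.000903). SPL14 also did not pass with array weights (0.0533), GRF4 with median centring (0.0537) and SLRL1 with quantile normalization (0.0561).

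No member passed the test in the lists of cytokinin (26 genes), tapetum and pollen wall (9), photosynthesis (10), secondary wall and lignin (6), histones and mitotic cyclins (13), ribosomal proteins (23), heat shock proteins (23), seed storage proteins (8) and homeobox and YABBY genes (22). Most hand-listed photosynthesis genes were not matched by name, among them all those listed as LHCA, LHCB and RBCS. Results for the photosynthesis list do not cover them. Adjusted over the list alone, 1 early anther and meiosis gene, 3 gibberellin genes, 3 auxin genes, 2 cytokinin genes, 3 heat shock genes and 2 WRKY and pathogenesis-related genes were higher, and 5 auxin genes, 1 photosynthesis gene, 2 heat shock genes and 1 homeobox or YABBY gene were lower. By camera none of the 15 other lists passed: the adjusted p was 0.0515 for ribosomal proteins (median -0.10), 0.0872 for WRKY and pathogenesis-related genes (0.12), 0.0935 for histones and mitotic cyclins (-0.12), 0.393 for gibberellin (0.01), 0.398 for photosynthesis (-0.08), 0.467 for early anther and meiosis (-0.15), 0.641 for auxin (-0.07), 0.698 for homeobox and YABBY genes (-0.05), 0.799 for tapetum and pollen wall (0.03), 0.91 for heat shock (-0.02), 0.927 for floral and meristem regulators (-0.05) and for seed storage proteins (-0.08), 0.983 for secondary wall and lignin (0.01) and for SBP, TCP and GRF factors (-0.004), and 0.988 for cytokinin (0.001). Ribosomal proteins passed with an intensity trend and robust estimation (0.021) and with the mean of probe sets (0.0491). With a sample left out, they passed camera without wild type replicate 1 (adjusted p = 0.0177), and WRKY and pathogenesis-related genes without osmads6-1 replicate 2 (0.0274) or wild type replicate 2 (0.0465). The photosynthesis median was -0.24 without wild type replicate 3 (adjusted p = 0.0712), and the gibberellin median 0.11 without osmads6-1 replicate 1 and -0.03 without wild type replicate 1. Median, mean and test differed in sign for floral and meristem regulators (mean -0.03, test higher), heat shock (mean 0.01, test higher) and cytokinin (mean -0.005, test higher).

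RNA controls on the array also differed between the genotypes, in the same samples as the genes that rose or fell. The gap between the 3 prime and 5 prime probe sets, which widens as RNA is degraded, was smaller in osmads6-1 for Gapdh (0.96 ± 0.14 against 1.54 ± 0.13 log2 units, SD, n = 3), actin (1.83 ± 0.21 against 2.09 ± 0.01) and cyclophilin (0.74 ± 0.07 against 0.94 ± 0.10), with no overlap between the groups. The actin difference of -0.27 was -0.15 without osmads6-1 replicate 1. An exact permutation test, two-sided, gave p = 0.1 for each of these 3 transcripts, the smallest that 3 samples against 3 allow. Batches are not given in the labels and were not analysed here.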

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

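The measures in this part, and their tests, were all chosen after values of the control probe sets were seen. In 7 measures of added transcripts and ribosomal RNA, which the comparisons above do not use, every osmads6-1 sample was higher than every wild-type sample. The 4 bacterial poly-A transcripts that Affymetrix kits add to RNA before labelling were higher by 0.62 (dap), 0.57 (thr), 0.49 (phe) and 0.53 (lys) on the log2 scale. Some called rises were smaller than any of these 4, such as RFL (0.47), GRF4 (0.42) and EXPA7 (0.44). Values were not scaled to the added transcripts, so such rises hold only relative to the other transcripts measured. The probe sets for 18S, 28S and 25S ribosomal RNA were higher by 1.14, 0.76 and 0.75. Without wild type replicate 1, which was low in all 3, these became 0.61, 0.36 and 0.21. An exact permutation test gave p = 0.1 for each of the 7, the smallest the design allows.

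Other control measures overlapped between the groups. The 5.8S ribosomal RNA differed by 0.14 (exact permutation p = 0.7), and -0.03 without wild type replicate 1. The hybridization controls bioB, bioC, bioD and cre, added after labelling, differed by 0.04, 0.11, 0.11 and 0.07 (exact permutation p = 0.9, 0.8, 0.8 and 0.8), and by -0.22, -0.17, -0.16 and -0.08 without wild type replicate 1, the lowest sample in each. In each control, osmads6-1 replicates 1 and 3 and wild type replicate 1 lay below the other samples. For bioB these were 8.64, 8.31 and 8.07. Osmads6-1 replicate 2 and wild type replicates 2 and 3 gave 8.86, 8.87 and 8.78. The first axis of a principal component analysis (45.7% of the variance) separated the genotypes. Values on it ran from -42.6 to -10.7 in osmads6-1 and from 18.6 to 32.5 in wild type. The second axis (23.3% of the variance) divided the samples as the hybridization controls did, across genotype. The cause of this division was not tested. The 3 prime minus 5 prime gap of the dap transcript did not separate the groups (1.81 ± 0.22 in osmads6-1 and 1.76 ± 0.08 in wild type, SD, n = 3; exact permutation p = 0.9).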

How the results depend on the processing

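The settings here were all listed in advance, but the named genes they were applied to, and the adjusted p as the value of each list, were chosen after results were seen. The cause of a change was not tested unless stated. The difference of OsMADS6 lay between 0.08 and 0.26 with a sample left out and never passed. With a sample left out, the calls ranged from 101 to 734 (51 to 512 higher, 50 to 222 lower), and those of at least 2-fold from 67 to 282 (28 to 224 higher, 39 to 58 lower), with fewer samples in each fit. Of the 668 calls, 98 to 457 were shared with each such fit. Of 43 called genes named in the text, 13 to 35 passed in each of these fits and 12 in all 6. All 43 kept their direction, which was fixed in advance, since the groups did not overlap in any called probe set. OsMADS15, not called, lay between -0.0071 and 0.111. Quantile normalization gave 724 calls and centring 595. The filter on dim probe sets gave 1203 calls (718 higher, 485 lower) over fewer tests, the trend with robust estimation 1508 (875 and 633), and array weights 1087 (710 and 377). An adjusted p of 0.01 left 93 (53 and 40; at least 2-fold 66, with 30 higher), and the test against a 1.5-fold change 36 (10 higher, 26 lower, all at least 2-fold: 36, 10 and 26). Replicate numbers did not pair the samples: same-numbered deviations correlated at 0.10, 0.26 and -0.20. With the replicate block 452 probe sets passed, 283 of them higher. Of the 43 genes 31 passed, and OsMADS2, RFL, SPL14, JAZ4, JAZ10, EXPA5, EXPA7, WRKY71, GRF4, OsMCM2, OsMCM7 and OspolD1 did not (adjusted p 0.0503 for WRKY71 to 0.0844 for GRF4); the floral homeotic MADS list had adjusted p = 0.0669, and cytokinin turned lower (0.93).

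The floral homeotic MADS list had adjusted p = 0.0679 with quantile normalization, 0.0900 with the dim filter, 0.061 with array weights, 0.0526 with the mean of probe sets and 0.595 with an estimated correlation, and 0.00813 to 0.0725 with a sample left out. Jasmonate had 0.0614 with quantile normalization, 0.116 with array weights, 0.595 with an estimated correlation and 0.0069 to 0.227 with a sample left out. Expansins had 0.0735, 0.116, 0.595, 0.0526 with the mean of probe sets, and 0.0109 to 0.224. Ribosomal proteins passed with the trend (0.021) and the mean of probe sets (0.0491), with 0.0177 to 0.234 with a sample left out, and the WRKY list ranged from 0.0274 to 0.227. Lists without a call turned direction: with the dim filter SBP, TCP and GRF factors, seed storage proteins and homeobox and YABBY genes (0.937 each), with the trend SBP, TCP and GRF factors (0.957), with array weights secondary wall (0.891) and with the mean of probe sets secondary wall (0.996). With a sample left out, direction also turned in SBP, TCP and GRF factors (0.501 to 0.981), cytokinin (0.832 to 0.974), floral and meristem regulators (0.501 to 0.932), heat shock (0.501 to 0.983) and secondary wall (0.718 to 0.982). Without detection calls, signal over background was not known, which limits dim genes such as OsMADS13.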

Other observations

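The lists and tests in this part were all chosen after the values were seen, so the list p-values are not independent evidence. Camera p-values of the 2 added lists were adjusted over these 2 alone, not with the 18 lists fixed in advance. Of 38 genes of the abscisic acid (ABA) and dehydration response matched by name, 10 rose, none fell and 28 did not pass (adjusted over the list alone, 22 rose), and 31 had a positive difference. As a set they passed at the preset correlation (camera adjusted p = 1.42e-11) and not with an estimated correlation (adjusted p = 0.0547). Beside PP2C68, RAB21 and RAB16B, those that rose included the protein phosphatases OsPP2C30 (2.92-fold, limma adjusted p = 0.00233), OsPP2C08 (2.47-fold, 0.00994) and OsPP2C09 (2.05-fold, 0.00687), the late embryogenesis protein Osem (2.51-fold, 0.00361), the bZIP factor OsABF2 (1.83-fold, 0.021) and the ABA hydroxylase OsABA8ox1 (5.09 ± 0.09 to 6.84 ± 0.75, adjusted p = 0.0396), dim in wild type, which leaves the size of its rise open. OsPP2C08 did not pass without wild type replicate 2 or 3 (0.0645 and 0.0536), OsABF2 passed only without osmads6-1 replicate 1 or 2 (0.0095 and 0.0282), and OsABA8ox1 only without osmads6-1 replicate 1 (0.000311). The list median was 0.29. The name pattern also took in OsRab5A, a vesicle GTPase.

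Of 30 genes of DNA replication, 7 fell, none rose and 23 did not pass (adjusted over the list alone, 17 fell), and 28 had a negative difference. As a set they passed at the preset correlation (camera adjusted p = 4.01e-12) and not with an estimated correlation (adjusted p = 0.104). Those that fell were OsORC3, the helicase subunits OsMCM2, OsMCM3, OsMCM4, OsMCM5 and OsMCM7, lower by 1.58-fold, 1.55-fold, 1.75-fold, 1.65-fold and 1.85-fold, and the polymerase gene OspolD1 (1.49-fold), with limma adjusted p of 0.0118 for OsORC3 and, for the others, from 0.0214 for OsMCM4 to 0.0479 for OsMCM3. With a sample left out, each of these MCM genes and OspolD1 passed only without osmads6-1 replicate 1, with adjusted p from 0.00537 for OsMCM4 to 0.0384 for OspolD1, and OsMCM3 also did not pass with median centring (0.0561). The list median was -0.37, and -0.23 without osmads6-1 replicate 2; per sample it was -0.25, -0.48 and -0.27 in osmads6-1 replicates 1, 2 and 3.

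The fall of the floral homeotic MADS genes was set against 2 other readings. A single mislabelled sample is argued against: each of the 6 samples was most similar to a sample with its own label (6 of 6). Correlations within and between the groups overlapped, though. An exchange of the whole groups would look the same, and OsMADS6 does not check it. An earlier stage of the mutant flowers could also lower these genes; the early anther and meiosis list did not decide it (camera adjusted p = 0.467, median -0.15). The 3 prime minus 5 prime gap of control transcripts also went with genotype in these samples (-0.35 log2 units on average). Its bearing on these genes was not tested and cannot be told apart from genotype. Loss of OsMADS6 function stays open as well, untested beyond the comparison itself. Readings beyond those named here were not examined.

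For the rises among ABA and dehydration genes, heat or handling stress of the mutant samples may be a source; the heat shock list did not decide it (camera adjusted p = 0.91, members both ways). A difference in RNA integrity may be another: the 3 prime minus 5 prime gap of 3 control transcripts was -0.35 log2 units apart on average, which goes with genotype in every sample and cannot be told apart from it. The list's median per sample was 0.24, 0.39 and 0.26 in osmads6-1 replicates 1, 2 and 3, and the Gapdh gap was 0.81, 1.07 and 1.01.

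For the falls among replication genes, a smaller share of dividing cells in the mutant flowers may account for the fall; histones and mitotic cyclins did not pass (camera adjusted p = 0.0935, 10 of 13 lower), which leaves it open. The same RNA integrity gap (-0.35) cannot be told apart from genotype here either.

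The other splits of the 6 samples into 3 and 3 were counted for the probe sets and for the 18 lists fixed in advance. The real split gave 668 probe sets and the highest of the others 0 by limma. In the other splits the genotype difference lies within the groups and widens their spread. Their 0 is therefore no measure of how many calls arise by chance. Up to 5389 in another split had an unadjusted limma p under 0.05, against 7788 in the real split. That other split, osmads6-1 replicates 1 and 3 with wild type replicate 1, is the division seen in the hybridization controls. Of 10 splits, 1 gave as many as the real one, which is itself. For the lists the real split called 3 by camera, and the highest of the others also 3 (osmads6-1 replicates 1 and 3 with wild type replicate 2); 6 of the 9 other splits called at least 1 list, and 2 of 10 splits, the real one included, called 3. In both counts 10 splits are too few for a share under 0.05.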
